A study of Solanum tuberosum with 4 samples.

How the data were processed

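Gene expression was measured in leaves of the potato cultivar Désirée on 4 2-colour cDNA microarrays, on which fluorescent cDNA made from 2 RNA preparations is hybridised to the same spots and the ratio of the 2 dyes is read for each spotted clone. Per the labels' protocols, plants raised in vitro and kept in pots for 2 months received 75 mL of 150 mM NaCl or the same volume of tap water, and the first and second leaves were frozen on day 3. RNA preparations with an RNA integrity number under 7 were left out by the authors, and 15 µg of each was reverse transcribed and coupled to Cy3 or Cy5, per the labels' protocols. Each array carried 1 control and 1 salt RNA. Per the labels, the salt RNA was in Cy3 on replicates 1 and 3 and in Cy5 on replicates 2 and 4, so that the dyes were swapped between 2 arrays and the other 2. The labels describe 4 biological replicates per treatment and also 2 sets of plants, without saying which replicate came from which set.

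The deposited value table gives 1 log ratio per clone and array for 11507 clones, read here as log2 values. The scanner, background correction, normalization method, spot filter, logarithm base and numerator of the ratio are not given in the sources used here. A base of 2 was assumed because the ratios of each array lie around 0 and within about 4 units, and all fold values rest on that assumption, while p-values do not depend on it. Blank cells were left as missing. A second deposited table gives 1 p-value per clone from a one-sample t-test, per the file headers. These p-values were recomputed from the value table to within 0.01 for 10076 of 10081 clones with a value on at least 2 arrays. The other 1426 clones, with fewer than 2 values, have a deposited p of 1. No spot intensities were used here, so the signal behind each ratio is unknown, and the number of arrays limits the precision.

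All 4 arrays correlated positively although the dyes were swapped, and the authors tested the same values against 0. The ratios were therefore taken as already turned to 1 common direction. This is an assumption, because dye bias of single clones would also make unturned ratios correlate positively. Whether the common direction is salt over control or control over salt stayed open. The array titles name control first, whereas control is channel 1 on every array and the second channel over the first is a usual form of such ratios. Signs are accordingly reported as positive or negative ratios.

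The ratios were used as deposited. Clones with a value on at least 3 of the 4 arrays were fitted with limma 3.58.1 in R 4.3.3 as 1 group whose mean log2 ratio was tested against 0 (lmFit and eBayes, two-sided), and a clone was called at a Benjamini-Hochberg adjusted p under 0.05. The test, this threshold, the alternatives and the rule for named clones were set before the data were examined. The rule named, on each side, the largest called changes with the same sign on every array. For clones that carry only an ID the preset rule allowed more of them, and a narrower limit of the 2 largest on each side was applied here. None of the 11507 clone IDs occurs in the potato gene table used for names (assembly SolTub_3.0), so no clone is given a gene name. For the same reason, 27 lists of leaf pathways and cell types, fixed as keywords in gene descriptions, had no members that could be tested.

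The fit was tested on simulated data for the 7099 clones with 4 values, drawn with the clones' own spread, in which 200 clones were changed. It called 49 of 100 clones changed by 0.5 and 85 of 100 changed by 1 on the log2 scale, together with 6 of 6899 unchanged clones. With an adjusted threshold the share found depends on how many clones are changed, so these figures hold for that setting only. The simulated arrays were independent, whereas replicates 1 and 2, and 3 and 4, deviate together in the data, so these figures do not cover calls that such pairing would add. Alternatives covered leaving out each replicate, a dye term, other limits on missing values, centring and scaling of arrays, a robust variance model, array weights, other thresholds, an unmoderated test per clone and the opposite sign. A pair of alternatives that join replicates 1 and 2, and 3 and 4, was added after seeing the data. Intervals of shares of called clones are Wilson intervals, and those of variance and covariance ratios are from 1000 bootstrap draws over blocks of clone IDs or over clones (Python 3.11.15, numpy 2.4.6, scipy 1.17.1). Clones of the same gene may be spotted more than once, so counts of clones are not counts of genes.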

Results

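The response of potato leaves to salt was measured on day 3 after watering with 150 mM NaCl, in 4 arrays that each compared 1 salt-treated with 1 water-treated leaf RNA. Désirée is a cultivated potato grown for its red-skinned tubers. Of 11507 spotted cDNA clones, 7099 had a ratio on all 4 arrays, 2002 on 3, 980 on 2, 344 on 1 and 1082 on none. Replicate 1 gave a ratio for 9168 clones, replicate 2 for 10137, replicate 3 for 9461 and replicate 4 for 7940. The median log2 ratio was 0.042, -0.008, 0.022 and -0.002 on replicates 1 to 4, and the SD over clones lay between 0.363 and 0.403. A negative ratio stands for a lower level in salt-treated leaves if salt is the numerator and for a higher level if control is. The numerator is not given in the sources used here, so each direction below can be read with the sign turned.

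With the ratios taken as turned to 1 common direction, salt-treated and control leaves differed in 1190 of 9101 tested clones, or 13.1%. Of these clones, 743 (62.4%) had a negative ratio and 447 (37.6%) a positive one. The negative share was 53.1% of the 2488 clones with an unadjusted limma p under 0.05. The median called clone differed 1.51-fold on the negative side and 1.42-fold on the positive side, and 76 negative but 13 positive calls reached 2-fold. The largest differences were 4.55-fold on the negative and 3.32-fold on the positive side. Calls were made with limma at a Benjamini-Hochberg adjusted p under 0.05. The smallest called difference was 1.24-fold, and 538 calls reached 1.5-fold, 393 of them negative and 145 positive. With the sign of all ratios turned, the same calls comprise 743 positive and 447 negative clones. The count was 754 without replicate 1, 696 without replicate 2, 745 without replicate 3 and 799 without replicate 4, and negative calls outnumbered positive ones in each of these fits. With replicates 1 and 2, and 3 and 4, each averaged to 1 value, the count was 381 of the 7099 clones with 4 values. For the same clones with the 4 arrays kept apart it was 1333.

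**Figure D1:**
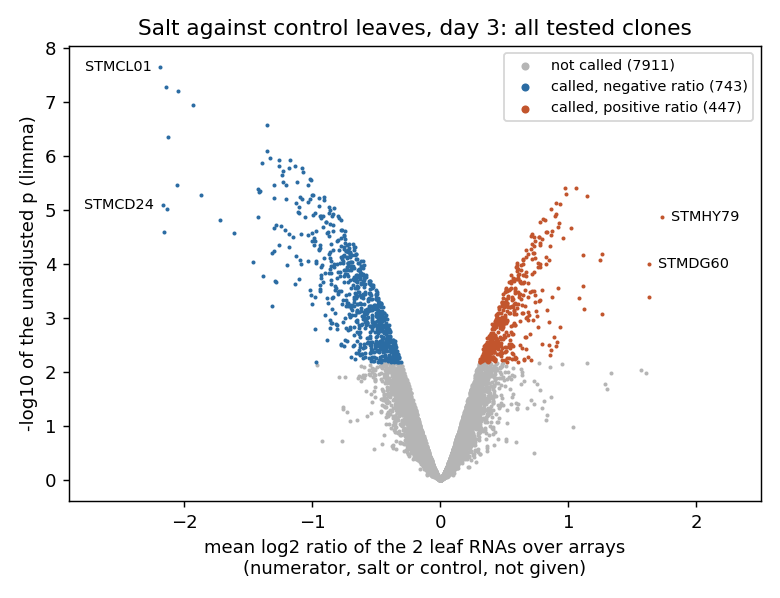
Mean log2 ratio of each of the 9101 tested clones (x axis) against the -log10 of its unadjusted limma p (y axis). Each point is 1 clone; the 743 called negative and 447 called positive clones are coloured, the negative side reaches farther from 0, and the 4 named clones are labelled.

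The clone with the largest difference, STMCL01, had a log2 ratio of -2.19 ± 0.177 (SD, n = 4), which is 4.55-fold, with a limma adjusted p of 0.000189. Its ratios were -2.42, -2.22, -2.0 and -2.11 on replicates 1 to 4. Clone STMCD24 had a ratio of nearly the same size, -2.16 ± 0.634 (SD, n = 4; limma adjusted p = 0.0015), but with more spread between arrays. Its values were -2.81 and -2.61 on replicates 1 and 2, against -1.64 and -1.60 on replicates 3 and 4. On the positive side, clone STMHY79 had a log2 ratio of 1.73 ± 0.524 (SD, n = 4; limma adjusted p = 0.00169), or 3.32-fold. It was higher on replicates 1 and 2, at 2.37 and 1.94, than on replicates 3 and 4, at 1.31 and 1.30. Clone STMDG60 had a log2 ratio of 1.63 ± 0.684 (SD, n = 4; limma adjusted p = 0.00403), or 3.10-fold, with the opposite order, 1.02 and 1.08 on replicates 1 and 2 against 2.06 and 2.36 on replicates 3 and 4. Without the variance shared over clones, the per-clone test gave adjusted p = 0.0924 for STMCD24, 0.0939 for STMHY79 and 0.137 for STMDG60, so these 3 calls rest on limma's pooled variance. The limma values above also take the 4 arrays as independent. With replicates 1 and 2, and 3 and 4, each averaged, limma gave higher adjusted p-values. They were 0.0128 for STMCL01, 0.0266 for STMCD24, 0.0278 for STMHY79 and 0.0352 for STMDG60.

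**Figure D2:**
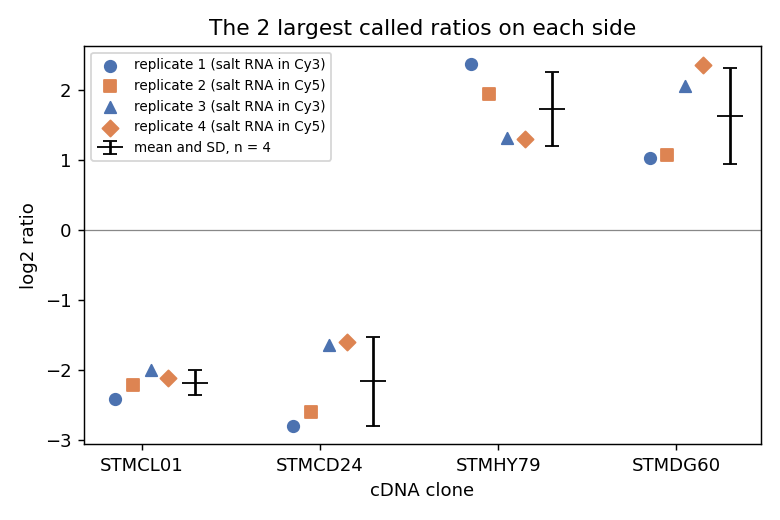
Log2 ratio (y axis) of the 2 largest called clones on each side (x axis) on each of the 4 arrays, coloured by the dye that carried the salt RNA, with the mean and SD. Clones were chosen among those with the same sign on every array, so each keeps 1 sign under both dye orientations. The values of STMCD24, STMHY79 and STMDG60 lie closer within replicates 1 and 2 and within 3 and 4 than between them.

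Of the 7099 clones with 4 values, 1480 were positive and 1417 negative on every array, together 40.8%. Signs independent between 4 arrays would give 12.5%, but arrays that deviate in pairs raise that value. The mean of replicates 1 and 2 had the same sign as the mean of replicates 3 and 4 in 4830 clones (68.0%), where independent signs of the 2 means would give 50%. Calls were concentrated in clones with complete data. The test called 1150 of 7099 clones with 4 values (16.2%) and 40 of 2002 clones with 3 values (2.00%).

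Arrays differed in how closely they agreed. Over the 7099 complete clones, which are not independent replicates, Pearson's r was 0.704 between replicates 1 and 2 and 0.718 between replicates 3 and 4, both of which are pairs of opposite dye orientation. It was 0.550 between replicates 1 and 3 and 0.540 between replicates 2 and 4, which share a dye orientation, and 0.424 and 0.422 for the remaining pairs. The means of replicates 1 and 2 and of replicates 3 and 4 correlated with r = 0.566. The labels state 4 biological replicates but do not say which replicates share a set of plants. With replicates 1 and 2, and 3 and 4, as random blocks, 1030 clones were called, with a block correlation of 0.126. That fit applies 1 correlation to all clones and still treats the 4 arrays as separate values, so it may understate the pairing. A contrast here is the sum of the 4 log2 ratios of a clone, with 2 of the signs turned, divided by 4. Over complete clones, the contrast of replicates 1 and 2 against 3 and 4 had a variance of 0.0293, against 0.0162 between dye orientations. With each of these pairs averaged to 1 value, 381 of 7099 clones were called, 279 negative and 102 positive, against 1333 of the same clones with the 4 arrays kept apart. The lower count is the one that would apply if the 4 arrays held 2 independent samples.

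**Figure D3:**
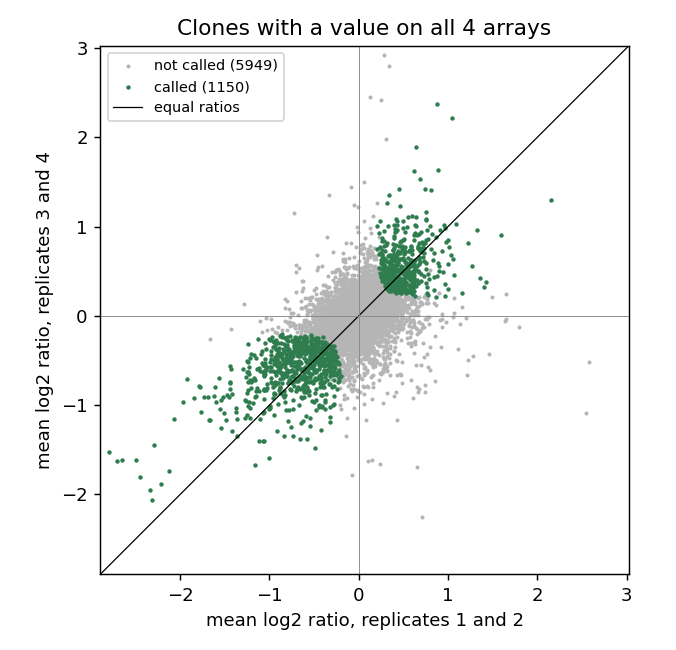
Mean log2 ratio of replicates 1 and 2 (x axis) against that of replicates 3 and 4 (y axis) for the 7099 clones with 4 values; each point is 1 clone and the line marks equal ratios. Over all points r was 0.566, and some uncalled clones lie far from 0 on 1 axis and near 0 on the other.

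Dye orientation was examined because a clone can take up the dyes unequally. In turned ratios, a constant dye effect cancels in the mean of a clone with 4 values but not in that of a clone with 3. With a dye term in the limma fit, 1028 clones were called, 648 negative and 380 positive, of which 986 were among the 1190. Of the 40 calls on clones with 3 values, 18 were also called with the dye term. A dye term on 3 values also leaves less information on the spread, so the other calls need not be owed to dye. The dye term itself passed an adjusted p under 0.05 for 0 clones by limma, and 601 of 9101 clones (6.60%) had an unadjusted p under 0.05 for it. This fit leaves the deviation shared within the array pairs described above in its residual. Over complete clones that deviation had a variance of 0.0293, against 0.0162 for the dye contrast. The 0 calls therefore do not show that dye effects of single clones were absent. The dye contrast varied more than the remaining contrast between arrays, which had a variance of 0.0067. The dye term would carry the salt response if the deposited ratios had not been turned to a common direction. In that case dye bias of single clones would be a source of the 1190 calls.

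The authors' deposited table lists a p-value under 0.05 for 2093 clones, 1062 with a negative and 1031 with a positive mean ratio in the value table. After Benjamini-Hochberg adjustment of the p-values of the authors' deposited table over the 10081 clones with at least 2 values, 70 were under 0.05 and 619 under 0.10. Of the 1190 limma calls, 1109 (93.2%) had a p under 0.05 in the authors' deposited table. Both tests set the same ratios against 0, so a large overlap follows from the shared values and is not independent evidence.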

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

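Of 11 results tested for a single array standing apart from the other 3 (7 properties of the arrays and the 4 named clones), 1 passed Dixon's limit, and chance alone passes about 1 in 20. The 99th percentile of the log2 ratios was 0.928 on replicate 4, against 0.881, 0.881 and 0.872 on replicates 1 to 3. Replicate 4 also had the fewest clones with a value, 7940, and the lowest single ratio, -3.94. Among the 1150 called clones with 4 values, 37 (3.22%) passed the same limit.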

How the results depend on the processing

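The count of 1190 called clones (447 positive, 743 negative) ranged from 696 to 799 when each replicate was left out in turn, with 227 to 278 positive and 469 to 560 negative clones. It stayed within 1.5 times, between 1028 and 1333, with a dye term, with values required on all 4 or on at least 2 arrays, with arrays centred or scaled, with a robust variance model, with array weights and with replicates 1 and 2, and 3 and 4, as random blocks. The share of negative calls was 62.4%, and 65.0% with each array centred on its median. It was 63.1% to 70.1% with each replicate left out, the highest without replicate 4, and 59.8% with values on all 4 arrays. It also moved with the threshold and the test: 53.1% at an unadjusted limma p under 0.05, 51.0% at an unadjusted p under 0.05 in the per-clone test, 57.2% at an adjusted limma p under 0.10, 71.5% at one under 0.01 and 73.2% with the pair means, on the same clones as the 59.8%. An adjusted p under 0.01 left 460 (131 and 329), and one under 0.10 gave 1741 (746 and 995). An unadjusted p under 0.05 gave 2488 (1168 and 1320), or 579 (172 and 407) with a 1.5-fold minimum. The per-clone one-sample test gave 2051 at an unadjusted p under 0.05, 1006 of them positive, and 106 after Benjamini-Hochberg adjustment (44 and 62). With the means of replicates 1 and 2 and of replicates 3 and 4 as 2 values, 381 were called (102 and 279), of which 380 were among the 1190. That setting and the random blocks were chosen after seeing the data. The random-block fit still treats the 4 arrays as separate values, so its count does not show that the pairing matters little. Fewer values per clone and stricter limits lower these counts by construction. With every sign turned, 743 calls were positive and 447 negative, STMCL01 and STMCD24 read 2.19 and 2.16, and STMHY79 and STMDG60 read -1.73 and -1.63. Over the other alternatives the 4 named clones kept their sign, which largely follows from choosing clones with 1 sign on every array. In these alternatives 3 adjusted p-values of the named clones were above 0.05, all in the per-clone test. Alternatives for the gene lists gave no value, as no list had members. No paired analysis was possible because the 4 arrays form 1 group, in which each ratio already sets 1 salt against 1 control RNA. Depth could not be examined, as no spot signal was used here.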

Other observations

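Clones with a negative ratio were unevenly spread over the ID series of the array, taken as the first 4 letters of the clone ID. In the STMC series 203 of 1292 tested clones (15.7%, 95% Wilson interval 13.8 to 17.8) were called with a negative ratio, against 44 of 1680 (2.62%, 1.96 to 3.50) in the STMG series. STMI (9.82%) and the small STMB series (24.2% of 33 clones) also lay above the other series combined, and STMD (6.19%) and STMH (5.00%) below (Fisher's exact test per series, two-sided, 18 tests, adjusted p from 2.3e-23 to 0.0415 for these 6 series). Shares of positive calls varied less, from 2.91% in STMJ to 6.11% in STMH, and STMJ was the series below the rest at an adjusted p under 0.05 (Fisher's exact test, adjusted p = 0.0062). Permuting whole blocks of IDs with the same first 5 letters over the 9 series gave p = 1e-05 for negative calls, the smallest that 100000 permutations can give, and p = 0.019 for positive calls. The 33 STMB clones form 1 such block, so Fisher's exact test took clones of 1 block as independent there. The direction reads the other way if control is the numerator, and clones are not independent replicates. The 10th percentile of the mean log2 ratio of clones with 4 values was -0.580 in STMC and -0.189 in STMG, and the 90th was 0.280 and 0.337. No explanation of the difference between series was tested, as the clones have no gene names here and the series were seen to differ before they were compared.

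The tests below were chosen after the result they bear on was seen, except the covariance of clones with a missing value, whose bound was set before. Replicates 1 and 2, and 3 and 4, deviated together. Noise that is independent between the 4 arrays, even if unequal, would give the contrast of replicates 1 and 2 against 3 and 4 the same variance as that of 1 and 4 against 2 and 3. The ratio of these variances was 4.38 (95% interval 3.97 to 4.84). In turned ratios, dye bias of single clones would make the dye contrast the largest, but the pair contrast had 1.81 times its variance (1.66 to 1.97). By the full difference between means of 2 arrays, 99 clones differed at least 2-fold between the pairs. That compares with 15 between dye orientations and 3 in the remaining contrast. The pairs were formed after replicates 1 and 2, and 3 and 4, were seen to correlate most. Ratios above 1 therefore follow from that choice, and the intervals cover clones, not arrays. The values describe how far the pair contrast exceeded the others and do not decide against these explanations. Plants, extracts or a working day shared within each pair, or a difference in salt response between the 2 sets of plants that the labels mention, stay open, and no test here separates them.

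Calls were rare among clones without a value on 1 array, at 2.00% against 16.2% for complete clones. Having 3 values in place of 4 does not account for all of this. When 1 value was removed from 2000 complete clones, 11.5% of them were called on average over 50 draws, with a lowest value of 10.3% and a highest of 12.8%. Over replicates 1 to 3, the mean covariance between arrays was 0.0116 for the 1262 clones without a value on replicate 4 and 0.0889 for complete clones, a ratio of 0.13 (95% interval 0.08 to 0.18), while the pooled SD within a clone was 0.292 against 0.263. This covariance comes from the same values that decided the calls of the clones without replicate 4, so it is not independent evidence on why calls were rare. Smaller measured changes in these clones remain a candidate explanation, and compression of dim spots or weaker true responses could both produce them.

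The array design allows 8 patterns of array signs, mirror images counted once, which is too few for a share under 0.05. The real pattern was the 1 with 1190 calls, and the highest of the other patterns gave 0. As all arrays correlated positively, turning single arrays moves their common part into the spread and out of the mean. Few calls in the other patterns would follow from any source of that common part, so no conclusion is drawn from them.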
